A study of Homo sapiens with 6 samples.

How the data were processed

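RNA was measured in 6 libraries of HaCaT cells, 3 treated for 24 h with TGF-β1 and 3 with TGF-β1 plus silymarin. Per the labels' protocols, RNA was extracted with a mirVana kit, poly(A) RNA was enriched and stranded Illumina mRNA libraries were made. The submitters' processing notes list bcl2fastq 2.18.12, cutadapt 1.15, TopHat2 2.1.1, featureCounts, Subread 1.5.2 and DESeq2. The genome build, the annotation release and the strand setting of the counting were not given in the sources used here.

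The authors deposited 1 table of 57281 genes with versioned Ensembl identifiers and gene names. Its values are a signal in normalized read counts: every value in a deposited column was a whole multiple of 1 step per library, within a tolerance of 1e-06 reads, and the step differed between libraries. This is the form of read counts divided by a size factor. Dividing by the step gave whole reads for 100% of values, and totals of 20240542 to 30279391 reads, in 5 libraries. In TGF-β1 replicate 3 the step was 1.01136, and 100% of values were whole multiples of it as well. The check of units used here did not accept a step so near 1, so no count model used that column. Some symbols are older names, such as CTGF, and 16 names are written as dates, a known effect of spreadsheet software. The authors' size factors put the libraries on a common scale, so a change in total RNA per cell would not be visible.

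The planned main test for raw counts was replaced by the one planned for normalized values. In R 4.3.3, limma 3.58.1 was fitted with a trended prior to log2(value + 1) with group as the only term, over all 6 libraries. Genes with at least 10 normalized counts in at least 3 libraries were tested (17296 genes). This filter was chosen once the unit was known. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called changed. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and they are given as TGF-β1 plus silymarin against TGF-β1. P-values measure the spread between the 3 replicates of each group, which the series' description calls biological. The 3 lists of genes with fewer than 3 measured members were left out of list tests.

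Before the data were examined, 38 gene lists, the tests and the other settings to be tried were fixed. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. Camera compared 35 lists with the other tested genes, with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the lists. Fry was run beside it. Named genes followed a rule fixed at the same time. It took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 normalized counts and groups that did not overlap. It added up to 4 members with the smallest p of each list that passed camera or had at least 3 called members, and 15 genes named in advance, among them VIM. Some genes that the rule names are not reported here. Members named because only 5 or fewer of a list moved one way, the markers of other cell types, and genes first named under the additional observations were chosen after their values were seen. Positions are those of GENCODE 29 on GRCh38, matched by identifier for 97.3% of tested genes, and they may differ from the build the authors used.

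The procedure was tested on simulated values for the genes of this comparison (17268 tested), drawn with Poisson noise and a dispersion of 0.004. It called 92 of 100 genes changed by 1.5-fold and 100 of 100 changed by 2-fold, and 5.88% of its calls were unchanged genes. The changed genes were drawn from those with a mean of at least 50 normalized counts. Noise was independent between genes with the same dispersion for all, and no simulated library deviated with GC content as silymarin replicate 2 did. The share of unchanged genes among the calls may therefore differ in the real data. In simulated lists, 4 of 4 shifted lists and 0 of 36 unshifted lists were called. These lists held random genes with independent noise. They cannot show how often the preset correlation gives false calls among correlated genes. The estimated correlation of the real list of cholesterol synthesis and LDL uptake genes was 0.469. The simulated dispersion was set near the common dispersion of 0.00377 that edgeR found in 5 libraries.

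The alternatives were TMM, upper quartile and library-size scaling, no filter, a filter of at least 5 CPM (counts scaled to library size) in 3 libraries, pseudocounts of 0.1 and 10, an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood), limma-voom and DESeq2 1.42.0 on the reads recovered from 5 libraries, and a correction for GC content and transcript length, which removed a spline trend per library from 16828 annotated genes. The edgeR test on recovered reads called 4661 of 17843 genes.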

Results

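The data are RNA-seq libraries from HaCaT cells, a spontaneously immortalised line of human skin keratinocytes. All cultures received transforming growth factor β1 (TGF-β1) at 10 ng/ml for 24 h, a treatment the submitters chose to model tissue re-epithelialisation. In 3 biological replicates TGF-β1 was given without silymarin, and in 3 it was given with silymarin at 31.25 µg/ml. Silymarin is an extract of milk thistle seed made up mainly of flavonolignans. Poly(A) RNA was sequenced, and the deposited table held 57281 genes with 1 column of size-factor normalized read counts per library. Reads recovered from the table came to 30006104 and 29050685 in TGF-β1 replicates 1 and 2. They came to 23766394, 20240542 and 30279391 in silymarin replicates 1, 2 and 3. The column of TGF-β1 replicate 3 was not accepted as reads, and 17246 genes in it had at least 10 normalized counts, against 16967 to 17189 in the other libraries. No library from cells without TGF-β1 was analysed here, so the values describe silymarin on top of TGF-β1 and not the response to TGF-β1 itself.

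The 2 groups lay apart on the first principal component, which carried 66% of the variance. Pearson correlations of log2 values, taken across genes, were 0.995 within the TGF-β1 group, 0.993 to 0.995 within the silymarin group and 0.981 to 0.983 between the groups. Genes are not independent replicates, so these correlations only describe the libraries. Silymarin replicate 2 stood apart on the second component, at 25.9 against -13.3 in both of the other silymarin libraries, and it was the shallowest library. Its deviation from the other silymarin libraries ran with GC content across 16828 genes, with a Spearman correlation of -0.56, whereas the correlation with transcript length was 0.016. Every pair of replicates compared as reads differed by more than sampling noise, with a chi-square per degree of freedom of 2.76 for TGF-β1 replicates 1 and 2 and from 2.51 to 11.2 among the silymarin replicates. None of these 4 pairs was therefore taken for repeated copies of 1 library. TGF-β1 replicate 3 was not compared in this way, and all 6 libraries were kept as the labels give them.

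**Figure D1:**
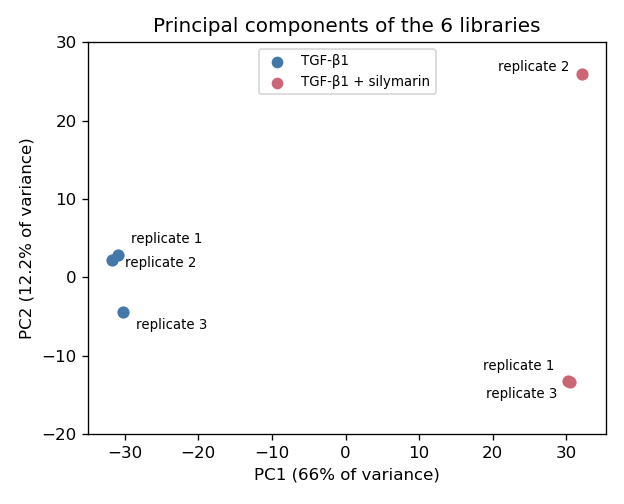
Principal components of the log2 values of the tested genes, with PC1 on the x axis, PC2 on the y axis and 1 point per library coloured by group. The groups separate on PC1 (66% of variance), and silymarin replicate 2 lies at 25.9 on PC2 (12.2% of variance).

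The comparison asked which transcripts silymarin altered in keratinocytes exposed to TGF-β1. With silymarin, 39 of 46 G2/M and mitosis genes, 22 of 36 extracellular matrix and collagen genes and 10 of 17 basal keratinocyte genes fell. MKI67 fell by 1.54 on the log2 scale (SE 0.069), FN1 fell by 0.98 (SE 0.049), KRT14 fell by 1.14 (SE 0.055) and KRT1 fell by 4.74 (SE 0.19). In the other direction, 30 of 40 ATF4 and amino acid response genes, 21 of 24 cholesterol synthesis and LDL uptake genes and 19 of 33 NRF2 target genes rose, with ASNS up by 2.19 (SE 0.078), IDI1 by 0.98 (SE 0.058) and SLC7A11 by 1.82 (SE 0.071). These 6 lists passed camera with a preset correlation and none passed with an estimated correlation (adjusted p = 0.184 for the G2/M list and adjusted p = 0.271 for each of the others). SLC7A11 and SESN2 belong to both the ATF4 and the NRF2 list, so the rises of those lists are not independent. The NRF2 target NQO1 did not pass the threshold in the main fit (limma adjusted p = 0.0837). The fixed set of TGF-β/SMAD target genes moved in both directions.

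In the limma fit, 5912 of 17296 tested genes changed at an adjusted p under 0.05 (34.2%), of which 2764 were higher and 3148 lower with silymarin. Most changes were small: the median log2 fold change was 0.37 among the genes called higher and -0.46 among those called lower, and 765 genes changed by at least 2-fold, 235 up and 530 down. The groups did not overlap for 47.1% of tested genes, against 10% by chance for 3 libraries against 3. Without silymarin replicate 2, 7227 genes changed (3516 higher, 3711 lower). A correction for GC content and transcript length that also recentred each library gave 4332 higher and 3286 lower, while the same correction without recentring gave 3600 and 3746.

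Among genes with a mean normalized count of at least 50, the deepest fall was that of KRT1, a suprabasal keratin (chromosome 12, 52674736 to 52680407, GRCh38), from 1392 ± 203 to 53.05 ± 19.6 normalized counts (SD, n = 3 per group; adjusted p = 7.5e-10). DSG4, a desmosomal cadherin (chromosome 18, 31376777 to 31414912), went from 3794 ± 157 to 230 ± 24.4 (log2 fold change -4.04, adjusted p = 1.4e-12). The antisense gene RP11-534N16.1 spans DSG4 on the opposite strand and fell by 3.84. The strand setting of the counting was not given in the sources used here, so reads of this pair may be shared. Secreted proteases made up part of the same group. MMP13 (collagenase 3, chromosome 11, 102942995 to 102955734) dropped from 24545 ± 1669 to 2310 ± 453, with a log2 fold change of -3.43 and an adjusted p of 1.5e-10. The aggrecan-cleaving proteases ADAMTS5 and ADAMTS1 had log2 fold changes of -4.08 and -3.46. The estrogen sulfotransferase gene SULT1E1 fell by 3.43, and the log2 fold changes of EVPLL, the mitochondrial malic enzyme gene ME3 and FAM198B were -3.03, -3.02 and -3.00.

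On the rising side, the transferrin receptor gene TFRC (chromosome 3, 196027183 to 196082189) went from 11017 ± 887 to 47830 ± 2642 normalized counts (SD, n = 3; log2 fold change 2.12, adjusted p = 6.6e-11). It was the most abundant of the 10 genes with the largest rises. IGFN1 rose by 2.74, from 132 ± 6.86 to 887 ± 59.7, and ANGPTL4, an inhibitor of lipoprotein lipase, by 2.73, from 25.6 ± 4.36 to 174 ± 13.5. CHAC1, which degrades glutathione, rose by 2.66, and ASNS, asparagine synthetase, by 2.19. TFPI2 and the lysyl oxidase gene LOXL2 rose by 2.26 and 2.25, CDH5 by 2.178, RP11-60L3.1 by 2.175 and RHOF by 2.11.

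**Figure D2:**
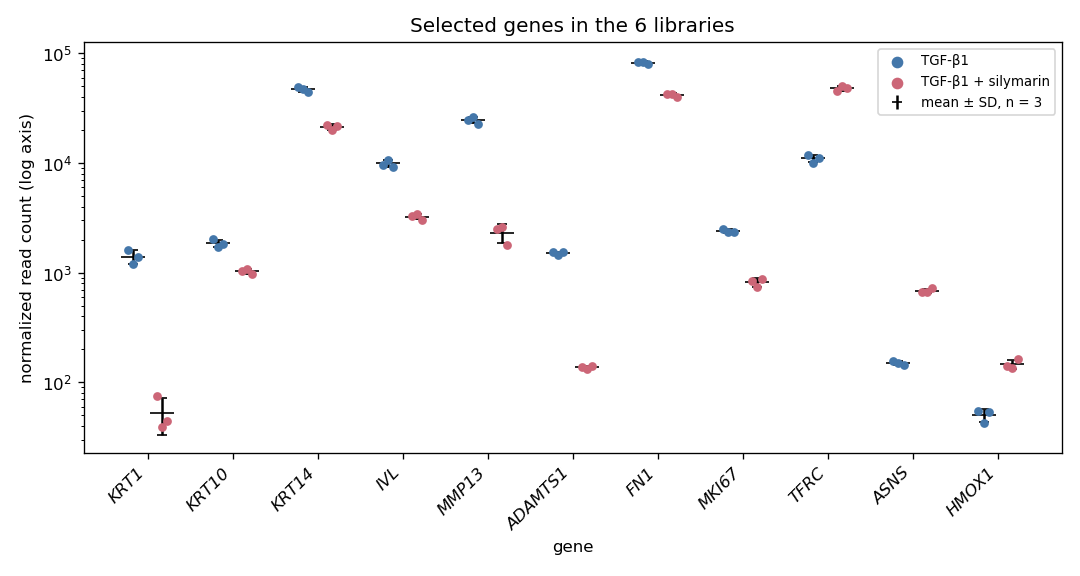
Normalized read counts (y axis, log scale) of selected genes in each library (points, coloured by group), with the mean and SD of 3 replicates as horizontal and vertical lines. MMP13 lies near 24545 in the TGF-β1 libraries and near 2310 with silymarin, and TFRC lies near 11017 and 47830.

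Of 46 measured G2/M and mitosis genes, 39 fell, 2 rose and 5 did not pass the threshold (40 fell and 2 rose when adjusted over the list alone), and their median log2 fold change was -0.85. KIF20A, a kinesin of cytokinesis, fell by 2.04. The log2 fold changes of the proliferation marker MKI67, the spindle gene ASPM and TOP2A, the topoisomerase of chromosome condensation, were -1.54, -1.24 and -0.95. The 2 that rose were FOXM1, a transcription factor of this programme, and BUB3, but 0 rose without TGF-β1 replicate 2 or 3 or silymarin replicate 3, and 1 rose without TGF-β1 replicate 1 or silymarin replicate 1. The list stood below the other tested genes by camera (adjusted p = 7.8e-18; adjusted p = 0.184 with an estimated correlation). In the G1/S and DNA replication list, 13 of 41 measured genes rose, 7 fell and 21 did not pass (14 rose and 8 fell adjusted over the list alone), with a median of 0.12 and no list call (adjusted p = 0.131). CCND1 rose by 0.60, CDC6 by 0.87, CCNE1 by 0.91 and PCNA by 0.33. Among 10 measured histone genes whose main transcripts lack a poly(A) tail, 5 fell (3 without TGF-β1 replicate 1) and none rose (6 fell adjusted over the list alone; camera adjusted p = 0.00664; adjusted p = 0.271 with an estimated correlation). HIST1H1C fell by 0.91 and HIST1H2BC fell by 0.85. Poly(A) selection captures such transcripts incompletely, and reads of near-identical histone genes may be shared.

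Keratinocyte genes were mostly lower with silymarin. In the differentiation and cornification list, 18 of 33 measured members fell, 7 rose and 8 did not pass (19 and 9 adjusted over the list alone). Beside KRT1, the cornified envelope genes IVL (9885 ± 765 to 3241 ± 186 normalized counts, SD, n = 3) and SPRR1B had log2 fold changes of -1.61 and -1.95. Those of the cross-linking enzyme gene TGM1 and of KRT10 were -1.57 and -0.85. The basal list had 10 of 17 members lower, with 3 higher (NGFR, EGFR and ITGB1) and 4 not past the threshold, and the same counts when adjusted over the list alone. The number higher was 1 without TGF-β1 replicate 2 or 3 and 5 without silymarin replicate 2. ITGA6 and DST, components of the hemidesmosome, had log2 fold changes of -1.08 and -1.07, and the basal keratins KRT14 and KRT15 of -1.14 and -0.94. Epithelial junction genes fell in 17 of 28 cases and rose in 4, CLDN4, CLDN7, TJP1 and DSG2, with 7 not past the threshold (18 and 5 adjusted over the list alone). The tight junction gene CLDN1 fell by 1.66, and the desmosomal genes DSC2 and DSP had log2 fold changes of -0.89 and -0.65. CDH1, which encodes E-cadherin, had a log2 fold change of -0.14 (adjusted p = 0.0428). That call was lost without TGF-β1 replicate 1, 2 or 3 or silymarin replicate 1, at adjusted p of 0.17, 0.0903, 0.115 and 0.144, and with library-size scaling or no filter (adjusted p = 0.065 and 0.0847). Wound-activated keratinocyte genes were lower in 12 of 22 cases and higher in 7, with 3 not past (12 and 7 adjusted over the list alone). MMP10, SERPINE2 and KRT6A had log2 fold changes of -1.99, -1.39 and -1.16. Reads of KRT6A and of other near-identical keratins may be split between copies. The differentiation, basal, junction and wound lists passed camera at adjusted p of 0.00533, 0.000609, 4.6e-05 and 0.0295, and each had an adjusted p = 0.271 with an estimated correlation. With a filter of at least 5 CPM in 3 libraries, the differentiation and wound lists no longer passed (adjusted p = 0.177 and 0.0863).

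Matrix genes were mostly lower. Of 36 measured extracellular matrix and collagen genes, 22 fell, 12 did not pass and only TIMP3 and P4HA1 rose (24 fell and 3 rose adjusted over the list alone). With the GC and length correction 4 rose and 22 fell, and with recentring as well 5 rose and 21 fell. FN1, fibronectin, dropped from 82111 ± 2604 to 41586 ± 1327 normalized counts (SD, n = 3; adjusted p = 7.4e-09), and TNC, tenascin C, fell by 1.54. TIMP3, an inhibitor of metalloproteinases, rose by 1.02. The list passed camera (adjusted p = 3.7e-07; adjusted p = 0.271 with an estimated correlation). In the Notch and Wnt list, 14 of 23 genes fell, 8 did not pass and only RNF43 rose (17 fell and 1 rose adjusted over the list alone). Without silymarin replicate 2 or with the GC and length correction, 2 genes rose. The list passed camera (adjusted p = 4.5e-06, and 0.184 with an estimated correlation). It holds receptors, ligands and antagonists beside targets, so its balance is no measure of Notch or Wnt signalling. NOTCH3 and JAG1, a receptor and a ligand of the Notch pathway, had log2 fold changes of -1.04 and -0.53, and the Notch target NRARP of -1.13. Actin cytoskeleton and motility genes fell in 14 of 40 cases, rose in 3, TLN1 and RND3 among them, and did not pass in 23, with the same calls adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.418 with an estimated correlation). MYLK, myosin light chain kinase, fell by 1.40 and TPM1 fell by 0.63, while TLN1, talin, rose by 0.45. Without silymarin replicate 2, 10 actin genes rose and 16 fell, with a median of -0.042 and an adjusted p of 0.106. With the GC and length correction, 10 rose and 18 fell (adjusted p = 0.0655).

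TGF-β/SMAD target genes showed no common direction. Of 33 measured, 9 rose, 13 fell and 11 did not pass (11 rose and 13 fell adjusted over the list alone; camera adjusted p = 0.514). With the GC and length correction 12 rose and 14 fell, and with recentring as well 15 rose and 14 fell. ANGPTL4 rose, whereas ID3, MMP2, THBS1 and the inhibitory SMAD7 fell, with log2 fold changes of -1.33, -0.92, -0.80 and -0.23. The list was not divided into genes that TGF-β1 raises and genes that it lowers. Its balance is therefore no measure of TGF-β signalling. CTGF (also named CCN2) had a log2 fold change of 0.18 and TGFB1 of -0.09, neither past the threshold (adjusted p = 0.145 and 0.327). Mesenchymal genes were likewise divided, with 6 up, 6 down and 7 not past of 19 (6 and 6 adjusted over the list alone; camera adjusted p = 0.438). LOXL2 rose, and SPARC fell by 0.72. The median of this list was -0.19 and its mean 0.024. VIM had fewer than 10 normalized counts in too many libraries to be tested. MMP9 fell by 0.34 (adjusted p = 0.00266).

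Of 40 measured ATF4 and amino acid response genes, 30 rose, 3 fell (SLC7A1, SLC38A2 and NUPR1) and 7 did not pass (32 and 3 adjusted over the list alone; camera adjusted p = 2.3e-13; adjusted p = 0.271 with an estimated correlation). ASNS went from 150 ± 6.005 to 686 ± 28.3 normalized counts (SD, n = 3; adjusted p = 4.4e-10), the serine synthesis gene PSAT1 rose by 1.76 and VEGFA by 1.30. NRF2 target genes rose in 19 of 33 cases, fell in 3 (GPX2, CBR1 and FTH1) and did not pass in 11 (21 and 3 adjusted over the list alone; camera adjusted p = 1.7e-07; adjusted p = 0.271 with an estimated correlation). FTH1 (adjusted p = 0.0394) lost its call without TGF-β1 replicate 1 or 2 or silymarin replicate 1 (adjusted p = 0.179, 0.1 and 0.071) and with no filter (adjusted p = 0.0649). The cystine transporter gene SLC7A11 went from 485 ± 26.8 to 1722 ± 131, the glutathione synthesis gene GCLC rose by 0.76, SQSTM1 by 0.79 and the haem oxygenase gene HMOX1 by 1.53. NQO1, often used as an NRF2 reporter, had a log2 fold change of 0.11 (adjusted p = 0.0837). It passed without silymarin replicate 2 and with library-size scaling (adjusted p = 0.0321 and 0.0452). It also passed with the GC and length correction, without and with recentring (adjusted p = 0.017 and 0.00303). The aryl hydrocarbon receptor list had 4 of 14 members higher, 7 lower and 3 not past (5 and 7 adjusted over the list alone), and no list call (adjusted p = 0.074). Its P450 genes CYP1A1 and CYP1B1 had log2 fold changes of -1.49 and -1.52 and ALDH3A1 of -1.59. This list passed with no low-value filter, with the 5 CPM filter and without silymarin replicate 3 (adjusted p = 0.015, 0.043 and 0.0441). Xenobiotic metabolism and transport genes rose in 8 of 24 cases and fell in 5, with 11 not past (8 and 5 adjusted over the list alone; camera adjusted p = 0.186). Without TGF-β1 replicate 1 or 2 or silymarin replicate 3, 3 of them fell. The retinoic acid hydroxylase genes CYP26A1 and CYP26B1 rose, CYP26A1 from 1.94 ± 2.03 to 26.9 ± 4.32 normalized counts (SD, n = 3; adjusted p = 0.000144) and CYP26B1 by 1.02.

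Of 24 measured genes of cholesterol synthesis and LDL uptake, 21 rose, PMVK fell and 2 did not pass, and 2 fell without silymarin replicate 2 or with the GC and length correction (21 rose and 2 fell adjusted over the list alone; camera adjusted p = 1.7e-12; adjusted p = 0.271 with an estimated correlation). IDI1 rose by 0.98, MSMO1 by 0.87, INSIG1 by 0.85 and FDFT1 by 0.81. Fatty acid synthesis and storage genes rose in 12 of 24 cases, fell in 2 (PLIN2 and FADS2, or 5 genes without silymarin replicate 3) and did not pass in 10 (12 and 5 adjusted over the list alone; camera adjusted p = 0.00139; adjusted p = 0.33 with an estimated correlation). FASN, fatty acid synthase, went from 37263 ± 1969 to 88622 ± 15898 normalized counts (SD, n = 3), LPIN1 rose by 1.23 and PNPLA3 by 1.13. Hypoxia and glycolysis genes were higher in 20 of 35 cases and lower in 6, with 9 not past (20 and 6 adjusted over the list alone; camera adjusted p = 0.000283; adjusted p = 0.33 with an estimated correlation). LDHA rose by 0.51, EGLN1 by 0.65 and PFKFB3 by 0.46. Fatty acid oxidation and PPAR target genes rose in 6 of 22 cases and fell in 5, with 11 not past (8 and 5 adjusted over the list alone; camera adjusted p = 0.548), ACAA2 falling by 0.97. The number of those that rose was 11 without silymarin replicate 2 and 10 with the GC and length correction.

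Ribosome biogenesis genes rose in 20 of 30 cases, 10 did not pass and none fell (20 and 0 adjusted over the list alone; camera adjusted p = 1.9e-06; adjusted p = 0.154 with an estimated correlation), with a median of 0.22. Without TGF-β1 replicate 1 or 2, 13 rose, and with the GC and length correction 20 rose and 1 fell. NCL, nucleolin, rose by 0.40, NOP14 by 0.46, DDX21 by 0.38 and DKC1 by 0.34. Of 58 cytosolic ribosomal protein genes, 13 rose, 45 did not pass and none fell (12 and 0 adjusted over the list alone; camera adjusted p = 0.00267; adjusted p = 0.33 with an estimated correlation). The number that rose was 21 without silymarin replicate 2, 5 without TGF-β1 replicate 3 and 4 with edgeR on 5 libraries, and the GC and length correction gave 20 higher and 1 lower. RPL13 rose by 0.31 and RPLP0 by 0.29. Processed pseudogenes may share reads with these genes. Immediate early genes rose in 16 of 35 cases, fell in 8 and did not pass in 11 (18 and 8 adjusted over the list alone; camera adjusted p = 0.00582; adjusted p = 0.271 with an estimated correlation). MYC went from 1255 ± 100 to 2661 ± 134 normalized counts (SD, n = 3; adjusted p = 3.6e-08), PHLDA1 rose by 1.44, ATF3 by 1.13 and DUSP4 by 0.98.

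Inflammatory genes diverged. Among 23 measured NF-kB and inflammatory genes, 10 rose, 5 fell and 8 did not pass (12 and 6 adjusted over the list alone; camera adjusted p = 0.131), and 6 rose without TGF-β1 replicate 1. IL1B rose from 7.17 ± 0.88 to 53.3 ± 8.75 normalized counts (SD, n = 3; adjusted p = 1.4e-06), LIF by 1.09 and TNFAIP2 by 1.02, whereas the neutrophil chemokine gene CXCL6 fell by 1.44. Interferon response genes rose in 8 and fell in 9 of 36 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.854). Without TGF-β1 replicate 2, 5 rose and 5 fell, and without silymarin replicate 3, 5 rose. IRF1 rose by 0.75 and EPSTI1 fell by 1.04. The interferon list had a median of -0.04 and a mean of 0.0025. Genes of the p53 response rose in 11 and fell in 8 of 30 cases (11 and 9 adjusted over the list alone; adjusted p = 0.648), TNFRSF10B rising by 0.64 and PLK2 falling by 0.76, and 5 fell without TGF-β1 replicate 2 or 3. Unfolded protein response genes rose in 3 of 24 cases, XBP1, EDEM1 and DNAJB9, and fell in 8 (3 and 9 adjusted over the list alone; adjusted p = 0.319), with CALR down by 0.58. With the GC and length correction 5 of these rose and 11 fell. Apoptosis regulators rose in 5 and fell in 6 of 28 cases, with the same counts adjusted over the list alone (adjusted p = 0.788), and 3 fell without TGF-β1 replicate 2 or 3. HRK rose by 1.32 and BMF fell by 1.11, both of which encode BH3-only proteins.

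The remaining lists had no call. Heat shock genes rose in 5 of 19 cases and HSPB1 fell by 0.52, with the same counts adjusted over the list alone (adjusted p = 0.12, and 0.0406 without silymarin replicate 2). With the GC and length correction and recentring, 9 of them rose (camera adjusted p = 0.0325). Autophagy and lysosome genes rose in 9 and fell in 9 of 36 cases, also adjusted over the list alone (adjusted p = 0.298), GABARAPL1 rising by 0.83 and CTSB falling by 0.51, and 5 fell without TGF-β1 replicate 2. Without silymarin replicate 2, 13 rose and 9 fell, and with the GC and length correction and recentring 15 rose and 8 fell. YAP/TAZ target genes rose in 7 and fell in 3 of 22 cases, again also adjusted over the list alone (adjusted p = 0.513), and 4 rose without TGF-β1 replicate 2 or 3. Nuclear genes of oxidative phosphorylation rose in 5 and fell in 3 of 37 cases (5 and 2 adjusted over the list alone; adjusted p = 0.742), and 29 did not pass. The number that rose was 2 without TGF-β1 replicate 3, 3 without silymarin replicate 1 and 8 without silymarin replicate 2, and 5 fell with the GC and length correction. Mitochondrially encoded genes rose in 5 and fell in 3 of 15 cases, with the same counts adjusted over the list alone (adjusted p = 0.291). Only 1 fell with TMM, upper quartile or library-size scaling or without silymarin replicate 3. Without TGF-β1 replicate 1, 2 or 3 or silymarin replicate 1, 3 rose and 0 fell, and without silymarin replicate 2, 8 rose. With the GC and length correction 4 rose and 5 fell. Their share of all normalized counts was 9.19% to 9.54% in the TGF-β1 libraries and 10.2% to 10.3% with silymarin. Of 5 measured metallothionein list genes, MT2A rose and MT1L fell (2 fell with the GC and length correction), also when adjusted over the list alone (adjusted p = 0.854).

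**Figure D3:**
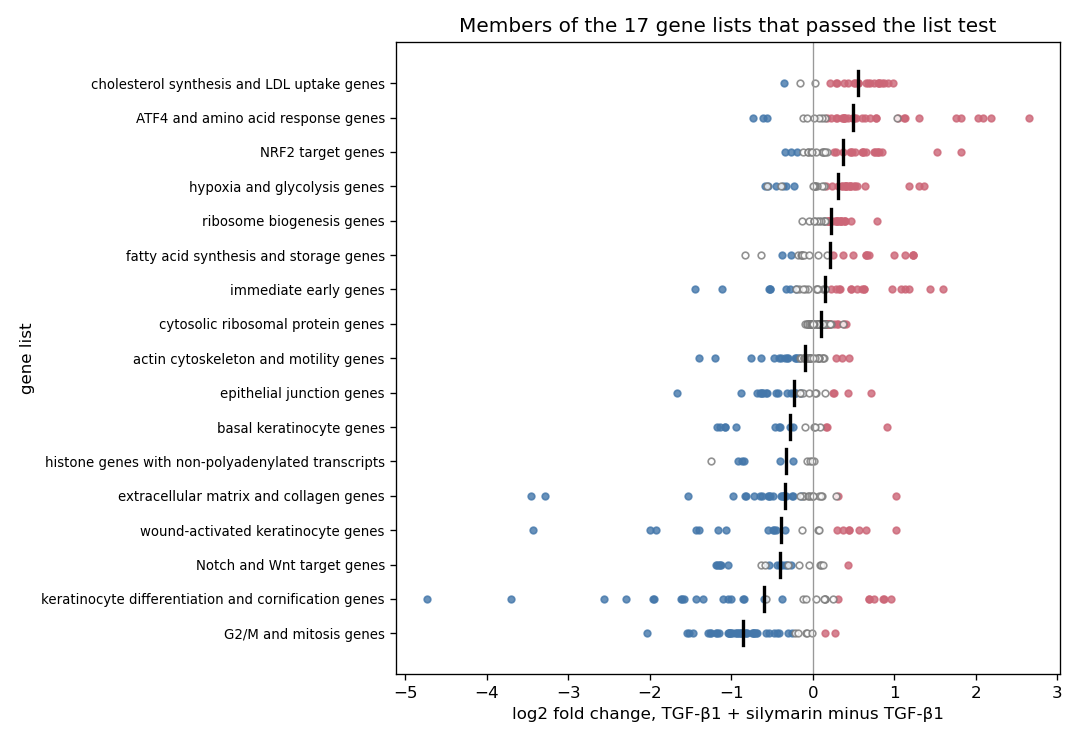
Log2 fold changes (x axis) of the measured members of each of the 17 lists that passed camera (y axis), with 1 point per gene, filled where the adjusted p was under 0.05 (blue lower, red higher with silymarin), and a black line at the list median. The medians run from -0.85 for G2/M and mitosis genes to 0.56 for cholesterol synthesis and LDL uptake genes.

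Markers of other cell types mostly stayed below 10 normalized counts. Fewer than 3 members of the fibroblast, melanocyte and immune lists were measurable, so those lists were not tested. FBLN2 went from a mean of 30.9 to 4.60 normalized counts, MITF from 146 to 247 and CD14 from 13.1 to 22.7 (adjusted p = 0.0492). PMEL, at 75.8 and 69.4, and CSF1R, at 33.5 and 33.1, did not pass (adjusted p = 0.511 and 0.974), and DCN, THY1, TYR and SOX10 were at 0 in both groups. Of 5 measured endothelial genes, CDH5 rose, from 34.1 ± 4.64 to 157 ± 8.27 (SD, n = 3), and ERG fell, also when adjusted over the list alone (adjusted p = 0.56). Without silymarin replicate 2, or with the GC and length correction, 2 of them rose, and without silymarin replicate 3, 2 fell. Across the 35 lists tested, camera with a preset correlation of 0.01 called 17, 8 higher and 9 lower, and with an estimated correlation it called 0, with a lowest adjusted p of 0.154. The deposited table held no fold changes or p-values of the authors' own, so no comparison with their calls was made.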

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

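Tests on 5 libraries and the GC and length correction were chosen after the data were seen. All 5912 called genes kept their sign under each scaling, pseudocount, block and left-out library. Much of this was fixed in advance. In 5796 of them the groups did not overlap, so a pseudocount or a left-out library could not turn the sign. A block leaves the fold changes as they were in this balanced design. Of the calls, 98.9% to 99% were shared with TMM and upper quartile scaling. Library-size scaling shared 96.1% and gave 3099 higher and 2918 lower. Leaving out 1 library gave 4390 to 7227 changed genes (1969 to 3516 higher, 2421 to 3711 lower) and 749 to 822 changed by at least 2-fold. At an adjusted p under 0.01, 3861 genes changed and 1667 were higher, by construction of the stricter threshold. DESeq2 on 5 libraries called 3489 genes, 1543 higher and 1946 lower. On the same 5 libraries limma called 4444 genes, edgeR 4661 and limma-voom 4675, so part of the drop from 5912 goes with the left-out library. The cause of the remaining difference was not tested. The GC and length correction with recentring gave 4332 higher genes. The number changed by at least 2-fold was 268 with the 5 CPM filter, which tested 11563 genes, and 449 with a pseudocount of 10, which shrinks low genes. With an estimated inter-gene correlation, 0 lists passed instead of 17.

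With the replicate number as a block, 5678 genes changed and 5489 of the calls were shared. CDH1 (adjusted p = 0.0738) and the 3 lower mitochondrially encoded genes lost their call. Deviations of same-numbered libraries correlated at -0.039, 0.042 and 0.023, and not every library correlated best with its own number. No sign of pairing was therefore seen. With 3 libraries per group and silymarin replicate 2 standing apart, these correlations cannot exclude it. Over 238 named or listed genes and their alternatives, 4354 of 4488 values kept their side of the threshold, 90 lost a call and 44 gained one. Of 559 list medians, 5 lost and 5 gained a call. Among genes and lists called in the main fit, 0 reversed. Changes of sign were not counted for the others. The median of the TGF-β/SMAD list, which had no call, went from -0.000585 to 0.0399 without silymarin replicate 2. Depth of 20240542 to 30279391 reads limits genes under 10 normalized counts, which were not tested.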

Other observations

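The gene groups in this part were put together after other values had been seen, so their tests are not independent of the data. The comparison of G1/S genes with the fall of mitotic genes was also chosen after its result was seen, and the alternatives with a GC and length correction were added later. Metalloproteinase and ADAMTS genes fell in 13 of 18 measured cases and rose in 3, MMP1, MMP17 and ADAMTS14. Beside MMP13, the macrophage elastase gene MMP12 went from 1634 ± 103 to 306 ± 64.3 normalized counts (SD, n = 3; log2 fold change -2.43, limma adjusted p = 7.8e-09), and MMP7 had a log2 fold change of -1.31. Ligands, antagonists and targets of BMP signalling fell in 10 of 14 cases and none rose. FST, follistatin, fell by 1.56, DLX3 fell by 0.80 and ID2 fell by 0.94, whereas ID1 had a log2 fold change of 0.06 (adjusted p = 0.458). The call of MMP1 was lost without TGF-β1 replicate 3 (adjusted p = 0.0866).

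Circadian clock genes rose in 8 of 12 measured cases and ARNTL fell by 0.44. DBP rose by 1.13, PER1 by 1.03, NR1D1 by 0.96 and NR1D2 by 0.78, genes activated by the CLOCK and ARNTL proteins. All cultures were treated for 24 h, so for clock genes a change in timing cannot be told from a change in level. The clock, metalloproteinase and BMP lists each had a camera adjusted p of 0.0455 over these 7 lists with an estimated correlation. The metalloproteinase list holds MMP13, ADAMTS1 and ADAMTS5, and the BMP list holds ID3, genes whose falls are reported above. Lists put together after values were seen, and adjusted over these 7 only, cannot be ranked against the lists fixed in advance. None of the lists fixed in advance passed with an estimated correlation (lowest adjusted p = 0.154). HAS3, a hyaluronan synthase, rose by 1.66, whereas HAS2 had a log2 fold change of 0.21 (adjusted p = 0.0608, and 0.0306 without silymarin replicate 3) and the hyaluronan list had 1 gene higher and 4 lower of 11. That balance depended on the fit: 4 were higher and 4 lower without silymarin replicate 2 or with the GC and length correction. With recentring as well, 6 were higher and 4 lower, and with library-size scaling 3 were higher and 3 lower. The lower call of SDC1 was also lost without TGF-β1 replicate 1, 2 or 3. Protease inhibitor and kallikrein genes were split 4 up and 4 down of 10, with KLK6 rising by 1.05 and the serpin gene SERPINB5 falling from 58800 ± 179 to 24830 ± 62.0 (SD, n = 3). TXNIP fell by 1.68, and IL1A rose by 1.75. The 6 libraries can be divided into 3 against 3 in 10 ways, and only 1 of them, the real one, called 5912 genes. The highest of the others called 1. With 10 splits no share under 0.05 is possible.

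The fall of G2/M and mitosis genes was set against technical explanations. After the GC and length correction, which raised the total number of calls to 7346, the median of the 46 genes was -0.85, and without silymarin replicate 2 it was -0.83. The value without silymarin replicate 2 argues against that library as the whole cause. Across 16828 genes the difference between the groups ran only weakly with GC content and length (Spearman correlations -0.14 and -0.022). The correction could therefore move the median little, and its outcome was largely set in advance. The weakness of that trend, rather than the corrected median, argues against GC content or length as the whole cause. A lower share of cycling cells at every phase would be expected to lower G1/S genes too, by an amount that is not known here. Their median was 0.12 (SD over genes 0.46, bootstrap interval over genes -0.084 to 0.27), so that list showed no fall as a whole in these libraries. Bootstrap intervals here and below resample genes, which are not independent replicates. They carry no spread between cultures. Histone genes had a median of -0.32 with 5 of 10 lower. Their main transcripts go with S phase but are captured incompletely by poly(A) selection. The share of cycling cells was not measured. That fewer cells enter G2/M with silymarin, or that transcription of these genes is lowered, may account for the fall, and neither was tested here.

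A second pattern was the rise of CYP26A1, CYP26B1 and STRA6 (log2 fold changes 3.52, 1.02 and 1.75), which retinoic acid is known to induce. After the GC and length correction their median was 1.81. The GC and length trend between the groups was too weak for the correction to remove such a rise, so this value is no separate test. If retinoic acid receptors were activated, other response genes would be expected to rise. Of 12 such genes not used to find the pattern, 5 rose and 4 fell. Their median was 0.037 (bootstrap interval over genes -0.35 to 0.55). It was 0.23 without silymarin replicate 2 and -0.069 without silymarin replicate 3. DHRS3 rose by 0.55 while RARB had a log2 fold change of -0.55, so the data leave receptor activation open.

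The rise of TFRC was examined as a sign that cells may lack iron, since iron shortage stabilises this transcript. An iron shortage strong enough to stabilise HIF would raise HIF target genes. The median of 15 HIF target genes not viewed before was 0.0895, with a bootstrap interval over genes of 0.0063 to 0.21. Both lay below the bound of 0.3 set beforehand. The median was 0.068 to 0.16 when 1 library was left out. A bound on that median was a poor choice for members that go both ways (6 rose and 2 fell, but 2 rose without TGF-β1 replicate 2 and 3 rose without TGF-β1 replicate 1), and the hypoxia and glycolysis list fixed in advance had a median of 0.31, so the HIF branch stays open. SLC11A2, some of whose transcripts carry an iron-responsive element, rose by 0.19, a call lost without TGF-β1 replicate 3 (adjusted p = 0.0861). The ferritin genes FTL and FTH1 had log2 fold changes of 0.17 and -0.19 (adjusted p = 0.0666 and 0.0394). Leaving out 1 library moved each ferritin gene across the threshold. Both are also in the NRF2 list, so their RNA is no measure of iron alone. The log2 fold change of TFRC was 2.1 after the GC and length correction. As the trend between the groups was weak, the correction could have removed little of this rise. A milder shortage of iron, or a rise that follows MYC or growth signalling, stays open and was not tested.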
